A study of Homo sapiens with 6 samples.

How the data were processed

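Poly(A)-selected RNA of SH-SY5Y cells was sequenced from 3 libraries labelled OTULIN KO and 3 labelled WT. The table holds a count and an FPKM value per gene and library. The counts are whole numbers per gene as the authors deposited them, not normalized. The FPKM values (fragments per kilobase, scaled to the mapped fragments) were also made by the authors, per the file headers, and their sums differ between libraries, with a mean of 425470 in KO and 283960 in WT. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d, DESeq2 and the genome build hg38, with no role or order. The annotation release and the strandedness of counting are not given in the sources used here. Antisense and overlapping genes, paralogs and pseudogenes can therefore share reads.

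Samples were grouped by the genotype in their titles. All columns were matched to a sample by library name. The chi-square of replicate pairs was 16.9 to 47.6 per degree of freedom, so no pair was 1 library counted again. The planned test for a file without counts was limma on log2(FPKM + 1). Because the file held counts, the test planned for that case was used: edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) with TMM factors and total counts as library sizes. Genes with a mean of at least 1 FPKM over the 6 libraries were tested (10820 of 32862), with genotype as the only term. Calls have a Benjamini-Hochberg adjusted p under 0.05. Standard errors are the absolute log2 change over the square root of the F statistic. CPM are counts scaled to the total of all counts in the library, and folds are ratios of mean CPM. For genes at 0 in all KO libraries the fitted change depends on the prior count and is no bound. The fold is then given against a floor of 3 counts over the KO group's 2398362 counts, 1.25 CPM. Intervals and floors cover counting error only, since no molecular identifiers are given.

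Counts were also simulated from the WT means in both groups, with the real library sizes and a common dispersion of 0.0269. There the test recovered 63 of 100 genes changed 2-fold and 93 of 100 changed 4-fold, with 5 false calls among 10620 unchanged genes. The simulation lacks the many zeros and the different composition of the KO libraries, so these rates do not carry over to the real comparison. Library measures were compared with an exact two-sided permutation test, whose smallest p for 3 against 3 is 0.1. For the KO libraries, 1 count is a larger share than for WT, and the floor per library was 3.48 to 4.13 CPM in KO and 0.0466 to 0.0486 in WT.

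There were 32 gene lists, fixed before the data were examined: linear ubiquitin signalling (LUBAC), NF-kB targets, interferon-stimulated genes, cell death machinery, tau and microtubule-associated proteins, tau kinases and phosphatases, neurodegeneration genes, autophagy, proteasome, SR and hnRNP splicing factors, spliceosome core, RNA decay, RNA polymerase II and general transcription factors, translation factors and tRNA synthetases, cytosolic ribosomal proteins, mitochondrially encoded genes, nuclear OXPHOS genes, integrated stress response, unfolded protein response, heat shock response, p53 targets, cell cycle, adrenergic and mesenchymal neuroblastoma identity, synaptic genes, nuclear export with paraspeckle and m6A genes, markers of epithelial cells, of blood and microglia, of glia and endothelium, replication-dependent histones, small structural RNAs and olfactory receptors. Older symbols were matched through RefSeq. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01. None of the 9 lists past the threshold stayed past it with an estimated correlation.

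Genes were named by a rule fixed before the data were examined. It took OTULIN and MAPT, and the 10 largest increases and 10 largest decreases on the log2(FPKM + 1) scale among called genes whose KO and WT values did not overlap. Clone, LOC, LINC, MIR, small RNA, antisense, divergent and pseudogene-style names were left out of these. It also took up to 4 called members of largest absolute log2 change per described list, or the 2 with the smallest p where none was called, and any member of the linear ubiquitin list. Genes outside the rule are marked as chosen after their values were seen. Some genes that the rule takes are not reported here.

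The alternatives were no filter, a mean of at least 5 FPKM, median-ratio scaling, quantile normalization, a TPM scale, limma with pseudocounts of 1 and 0.1 and with other variance models, DESeq2 1.42.0, a replicate block, an estimated correlation, and leaving out each library in turn. Added after the data were seen were limma on log2(FPKM + 1) as a full alternative, library totals without TMM factors, WT libraries thinned to the KO depth, and leaving out the 4 ribosomal RNA loci. Other computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and matplotlib 3.10.9 for figures.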

Results

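RNA was measured in SH-SY5Y, a human neuroblastoma cell line, by sequencing of poly(A)-selected RNA. The series compared gene expression between wild-type (WT) cells and cells in which OTULIN had been disrupted by CRISPR-Cas9, and its title concerns the expression of tau. OTULIN is a deubiquitinase that removes linear ubiquitin chains, and MAPT encodes tau, a microtubule-associated protein of neurons. There were 3 libraries labelled OTULIN KO and 3 labelled WT, all untreated. Their titles name no batch and do not say whether KO and WT libraries were prepared together. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

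The libraries differed greatly in depth. The 3 libraries labelled OTULIN KO held 809603, 862932 and 725827 counts, and the 3 WT libraries 62210442, 64352333 and 61772795, a ratio of the means of 78.5. Of the 32862 genes in the table, 2306, 2373 and 2567 had a count in the KO libraries against 27709, 27453 and 27958 in WT. There were 29202 genes at 0 in all 3 KO libraries and 67 at 0 in all 3 WT libraries. The 10 most abundant genes took 40.6% ± 7.0 of the counts in KO and 8.75% ± 0.13 in WT (SD, n = 3 each). Genes encoded by the mitochondrial genome took 0.00423% ± 0.00044 in KO and 8.52% ± 0.16 in WT. For each of these measures taken per library, the KO and WT libraries did not overlap, and the exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. On log2(FPKM + 1) values, the first principal component separated the groups and held 97.46% of the variance. Pearson correlations across genes, which are not independent replicates, were 0.938 to 0.946 within KO, 0.983 to 0.988 within WT and 0.105 to 0.129 between the groups. Depth and composition thus went with the genotype label in all 6 libraries, and no fold or list change given here can be assigned to the loss of OTULIN.

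**Figure D1:**
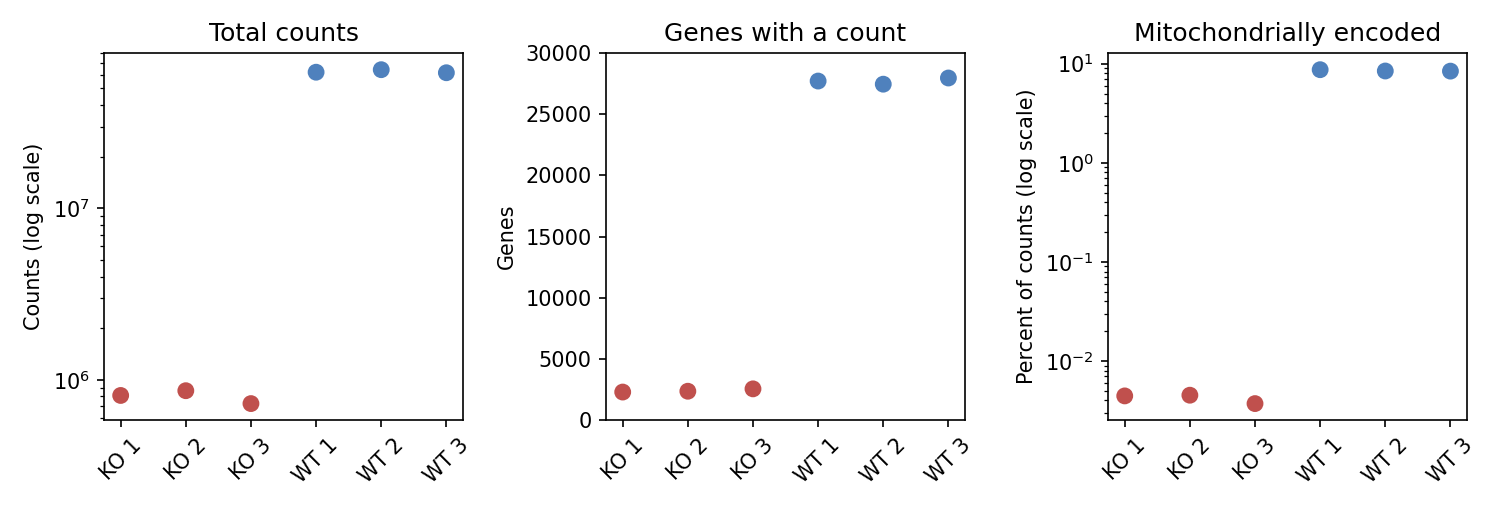
Total counts (log scale), number of genes with at least 1 count, and percent of counts in mitochondrially encoded genes (log scale), with 1 point per library. The 3 KO libraries lie between 725827 and 862932 counts and the 3 WT libraries between 61772795 and 64352333.

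OTULIN and MAPT were both at 0 counts in each of the 3 libraries labelled OTULIN KO. OTULIN (ENSG00000154124, chromosome 5, 14664664 to 14699850, plus strand, hg38) had 1682, 2101 and 2155 counts in WT, or 31.5 ± 4.0 CPM (counts scaled to the library total; SD, n = 3). MAPT (ENSG00000186868, chromosome 17, 45894527 to 46028334, plus strand) had 2945, 2794 and 2408 counts in WT, or 43.2 ± 4.2 CPM. Against the floor of 3 counts over the whole KO group, 1.25 CPM, OTULIN was at least 25.2-fold lower and MAPT at least 34.6-fold lower. The adjusted p was 0.00011 for OTULIN and 4.6e-05 for MAPT (edgeR quasi-likelihood test, Benjamini-Hochberg). At their WT share of the counts, 25.2 and 34.6 counts per KO library would have been seen. The absence of OTULIN does not check the labels, because most other genes were absent too. Of the 3138 genes with WT counts within 1.5 times of those of OTULIN, 2529 (80.6%) were also at 0 in all KO libraries, and for MAPT this held for 2556 of 3327 (76.8%).

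Genes called lower far outnumbered those called higher. Of 10820 genes with a mean of at least 1 FPKM, 10345 differed between KO and WT, 826 higher and 9519 lower in KO, and 475 did not pass the threshold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of the lower calls, 7629 were at 0 in all KO libraries. The 3 KO values did not overlap the 3 WT values for 10416 of the genes tested, where chance gives 10%. Only 115 tested genes had more raw counts in the 3 KO libraries together than in WT. After quantile normalization with limma the split was 4309 higher and 4479 lower (49.0% higher, against 7.98%). Of the 3193 genes called lower with edgeR and higher there, 2744 were at 0 in all KO libraries. These 2744 had no KO counts, so their higher calls came from the normalization. Among the 1496 genes with at least 30 counts over the KO group, the median log2 change was 0.57 with TMM factors, 0.96 with library totals alone and 0.01 with median-ratio scaling, so small changes depend on the scaling. All 3 KO libraries stand apart from WT in depth and composition, so no count of changed genes can be given without them.

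**Figure D2:**
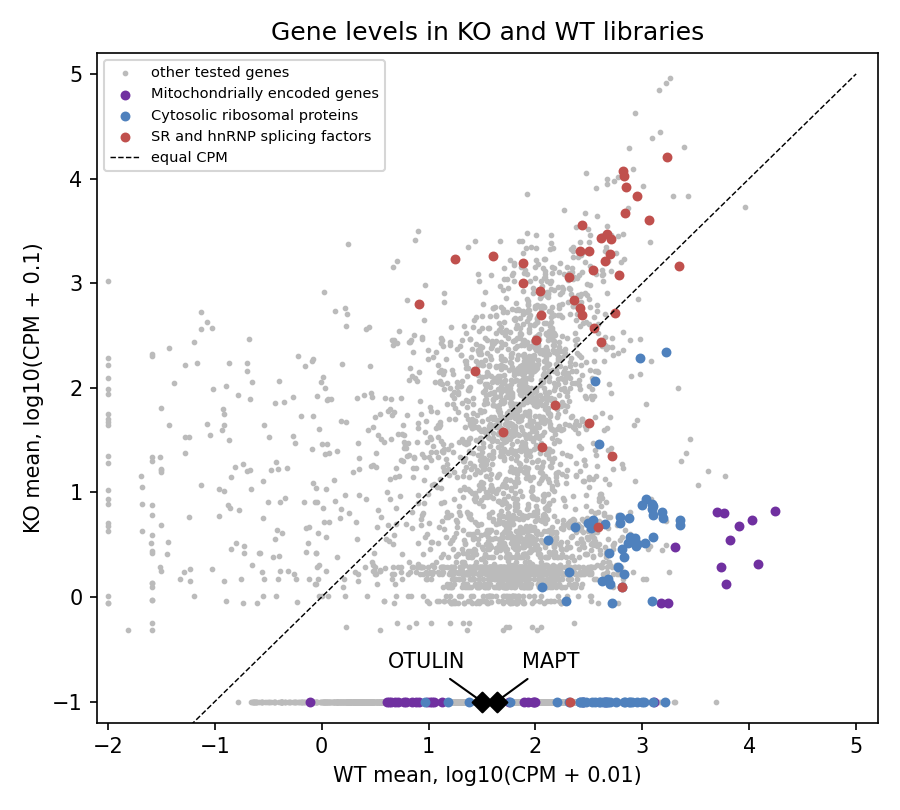
Mean level in KO (vertical, log10(CPM + 0.1)) against mean level in WT (horizontal, log10(CPM + 0.01)) for 10820 tested genes, with 1 point per gene, 3 gene lists coloured and the dashed line at equal CPM. The row of points at the bottom holds the 7716 genes at 0 in all KO libraries, OTULIN and MAPT (diamonds) among them.

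By the naming rule, the largest increases on the log2(FPKM + 1) scale were in NRN1 and MEST. NRN1, which promotes neurite outgrowth, was at 2584 ± 355 CPM in KO and 7.41 ± 0.21 in WT (SD, n = 3 each), 349-fold higher. MEST, an imprinted gene, was 399-fold higher at 3162 ± 348 against 7.92 ± 1.2 CPM. INSM1, a transcription factor of neuroendocrine cells, was at 524 ± 37 CPM in KO and 0.0648 ± 0.11 in WT, where its counts were 0, 0 and 12, so that without WT replicate 3 it was at 0 there. CITED2, a transcriptional coactivator, was 406-fold higher, the RNA-binding gene CPEB2 307-fold, the homeobox gene HOXC9 141-fold and the neuronal RNA-binding gene ELAVL2 92.6-fold. The remaining genes among the 10 largest increases were SETSIP, RAP1BL and HNRNPA1L3, at 907-fold, 227-fold and 94.8-fold higher. Their names mark them as relatives of SET, RAP1B and HNRNPA1, and reads shared with near-identical copies make these 3 values uncertain. The edgeR adjusted p for these 10 genes was at most 1.4e-05.

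Mitochondrially encoded genes made up all 10 of the largest decreases by the same rule. MT-CO1, a cytochrome c oxidase subunit, had 11, 3 and 2 counts in the KO libraries, 6.61 ± 6.1 CPM, against 17593 ± 202 CPM in WT, 2663-fold lower, or 5646-fold without KO replicate 1. MT-RNR2, the large mitochondrial ribosomal RNA, was 6113-fold lower on 2, 3 and 0 KO counts, or 9810-fold without KO replicate 2. MT-CO2 was 1967-fold lower on 6, 0 and 2 counts, or 4838-fold without KO replicate 1. MT-ND4 was 1961-fold lower on 3, 6 and 4 counts and MT-CO3 1718-fold on 4, 3 and 4. MT-ND2 was 2966-fold lower on 0, 0 and 4 counts, and at 0 in KO without KO replicate 3. MT-ND1 was 4946-fold lower on 3, 0 and 0 counts, with a 95% counting interval on the pooled counts from 1671 to 23678, and at 0 in KO without KO replicate 1. MT-ND4L was at 0 in KO and at least 1025-fold lower, and the mitochondrial tRNA genes MT-TY and MT-TN, also at 0, at least 76.3-fold and 78.5-fold lower. All 37 genes of this list were called lower. The list did not pass the camera test, which compares a list with all other tested genes, most of which were lower too (adjusted p = 0.074, or 0.61 with an estimated correlation). The same test gave 4.1e-06 without KO replicate 2 and 0.047 with library totals alone.

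Loci inside ribosomal RNA genes took a large share of the KO libraries. The loci ENSG00000281181, ENSG00000280614, ENSG00000280800 and ENSG00000281383 on chromosome 21 lie inside the 18S ribosomal RNA genes RNA18SN1, RNA18SN3, RNA18SN2 and RNA18SP5 and were chosen after their values were seen. The match is by position only, since all 4 are annotated as long non-coding RNAs on the minus strand and the strandedness of counting is not given. Together these 4 loci held 28.6% ± 8.6 of the counts in KO and 0.575% ± 0.22 in WT (SD, n = 3 each; exact permutation p = 0.1, the smallest possible). They are near-identical copies, so the split of reads among them is uncertain.

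Genes of linear ubiquitin signalling were mostly lower, as were 9519 of all 10820 tested genes, of which 7716 were at 0 in KO. Of 17 tested members of the list, 1 was higher, 15 were lower and 1 did not pass the threshold, and 14 were at 0 in all KO libraries. The 3 subunits of LUBAC, the ligase that builds linear chains, were at 0 in KO. RNF31 (WT 19.7 ± 9.0 CPM) was at least 15.7-fold lower, RBCK1 (53.5 ± 4.7) at least 42.8-fold and SHARPIN (34.0 ± 2.8) at least 27.2-fold. CYLD, another deubiquitinase of these chains, was at least 26.2-fold lower. TAB3 fell 11.2-fold on 0, 0 and 7 KO counts and was at 0 in KO without KO replicate 3. TAB2, an adaptor of the TAK1 kinase, was at 137 ± 19 CPM in KO and 75.3 ± 1.8 in WT, a log2 change of 0.46 (SE 0.09, edgeR adjusted p = 0.0020) that turned to -0.10 and lost its call with median-ratio scaling. MAP3K7, which encodes TAK1, had a log2 change of -0.27 (SE 0.18, edgeR adjusted p = 0.19) and was above 0 with library totals alone. As a list these genes did not pass the camera test (adjusted p = 0.96).

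Targets of NF-kB, interferon-stimulated genes and death genes were scarcely measured in KO. Of 5 tested NF-kB targets 4 were lower and 1 was not called, with NFKBIB at least 18.7-fold lower, the chemokine gene CCL2 at least 6.27-fold lower and SOD2 10.3-fold lower (camera adjusted p = 0.93). All 4 tested interferon-stimulated genes were lower, too few for a list test. Of 14 genes of the cell death machinery 13 were lower and 1 was not called (camera adjusted p = 0.35).

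Tau and other microtubule-associated proteins fell in most cases, as did 9519 of all 10820 tested genes. Of 31 tested members 2 were higher, 28 lower and 1 not called, and 18 were at 0 in KO (camera adjusted p = 0.63). The share of counts in the list went the other way, with 2.09% ± 0.26 in KO and 0.997% ± 0.024 in WT. STMN1, a tubulin-binding protein, was at least 741-fold lower, CRMP1 at least 434-fold, MAPRE1 at least 228-fold and DPYSL2 at least 221-fold. Chosen after their values were seen, MAP2 fell 13.5-fold, TUBB3 66.7-fold on 31, 0 and 0 KO counts, and STMN2 15.6-fold on 0, 53 and 106 counts. Without KO replicate 1 TUBB3 was at 0 in KO, and without KO replicate 3 STMN2 was 35.2-fold lower. MAP1B, likewise chosen later, was at 480 ± 99 CPM in KO and 357 ± 8.6 in WT (log2 change 0.02, SE 0.12, edgeR adjusted p = 0.86). Its direction turned with median-ratio scaling, where it was called lower (log2 change -0.53, edgeR adjusted p = 0.0084).

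Kinases and phosphatases that act on tau went both ways. Of 29 tested, 8 were higher, 18 lower and 3 not called. GSK3A and PPP1CA were at 0 in KO, at least 126-fold and 120-fold lower. Chosen after their values were seen, CDK5 was at least 56.6-fold lower, while PPP2CA, the catalytic subunit of protein phosphatase 2A, was 7.89-fold higher and CSNK1D 2.75-fold higher. GSK3B, also chosen later, was at 224 ± 6.1 CPM in KO and 129 ± 8.5 in WT (log2 change 0.41, SE 0.11, edgeR adjusted p = 0.0082), and turned to -0.15 without a call under median-ratio scaling. The list stood above other genes although its median change was below 0 (camera adjusted p = 0.0086, or 0.61 with an estimated correlation and 0.072 without KO replicate 2). With no filter on mean FPKM its direction turned.

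Splicing factors of the SR and hnRNP families were the list with the most members higher. Of 42 tested, 30 were higher, 11 lower and 1 not called, and the list took 9.83% ± 1.3 of the counts in KO and 1.81% ± 0.0084 in WT (SD, n = 3 each). NOVA1, a neuronal splicing regulator, rose 96.8-fold. Chosen after their values were seen, HNRNPH1 rose 15.6-fold, SRSF1 11.9-fold, HNRNPA2B1 9.35-fold and SRSF2 6.72-fold. HNRNPUL2 was at least 167-fold lower, HNRNPUL1 83.9-fold lower on 0, 0 and 10 KO counts, and PTBP1 556-fold lower on 3 counts (95% counting interval on the pooled counts from 176 to 2499). Without KO replicate 3 HNRNPUL1 was at 0 in KO, as was PTBP1 without KO replicate 2. The camera adjusted p was 3.1e-36, or 0.33 with an estimated correlation. By contrast, of 38 genes of the spliceosome core 2 were higher, 33 lower and 3 not called, with SNRNP200 at least 509-fold and PRPF8 at least 476-fold lower (camera adjusted p = 0.29, or 0.0041 without KO replicate 2).

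Genes of RNA decay were split. Of 55 tested, 14 were higher, 40 lower and 1 not called, with SMG5 at least 155-fold and LSM4 at least 141-fold lower. Chosen after their values were seen, CNOT2, a subunit of the CCR4-NOT deadenylase, rose 34.1-fold and PABPC1, a poly(A)-binding protein, 15.1-fold. The RNA helicase gene DDX5, outside the list and also chosen later, rose 19.3-fold. The list stood above other genes while its median change was below 0 (camera adjusted p = 0.018, or 0.61 with an estimated correlation and 0.075 without KO replicate 2). With no filter on mean FPKM its direction turned. Of 29 genes of nuclear export, paraspeckles and m6A, 5 were higher, 22 lower and 2 not called (camera adjusted p = 0.073, and between 0.021 and 0.025 without WT replicate 1, 2 or 3).

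Genes of ribosomal proteins, the cell cycle and respiration fell. Of 77 cytosolic ribosomal protein genes 76 were lower and 1 was not called, and 33 were at 0 in all KO libraries. RPL6 was at least 1306-fold and RPS3A at least 1002-fold lower. The list held 0.0714% ± 0.015 of the counts in KO and 5.21% ± 0.042 in WT (camera adjusted p = 1.9e-06, or 0.61 with an estimated correlation). All 40 cell cycle genes were lower and 34 were at 0 in all KO libraries (camera adjusted p = 0.0034, or 0.61 with an estimated correlation). MCM7 was at least 822-fold and the proliferation marker MKI67 at least 353-fold lower. For genes at 0 in KO the fitted change grows with the WT level. A downward camera result of a list with many such genes may therefore in part reflect high WT levels. Of 74 nuclear OXPHOS genes 72 were lower, 1 was higher and 1 was not called, with 62 at 0 in all KO libraries and UQCRH at least 149-fold lower. That list passed the camera test at an adjusted p of 0.035, which became 0.78 with an estimated correlation and 0.070 with median-ratio scaling. Of 56 translation factors and tRNA synthetases 6 were higher and 50 lower (camera adjusted p = 0.33, or 0.00066 without KO replicate 2). Their share of the counts was nonetheless larger in KO, at 5.31% ± 0.63 against 2.73% ± 0.069 in WT. Reads of ribosomal protein genes can be shared with their many pseudogenes, so their levels are uncertain.

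ACTB, the cytoskeletal beta-actin, had 5, 7 and 21 counts in the KO libraries, 14.4 ± 13 CPM, against 5980 ± 342 in WT, 415-fold lower, or 837-fold without KO replicate 3. GAPDH, a glycolytic enzyme, was at 23.6 ± 12 CPM in KO and 2568 ± 102 in WT. EEF1A1, a translation elongation factor, was at 5372 ± 880 CPM in KO and 9218 ± 196 in WT, while its pseudogene EEF1A1P5 was at 9862 ± 1352 and 465 ± 21. These 4 genes were chosen after their values were seen, and reads can be shared between EEF1A1 and its copy.

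Genes that mark the adrenergic state of neuroblastoma were lower in 30 of 32 cases and higher in 2. DBH, which makes noradrenaline, was at 1986 ± 139 CPM in WT and 0 in KO, at least 1588-fold lower. CHGA, a protein of secretory granules, was at least 581-fold lower and TFAP2B, a transcription factor, at least 572-fold. The regulator HAND2, chosen after its values were seen, was detected at 293 ± 34 CPM in KO, 3.23-fold lower. The camera adjusted p was 0.29, or 0.0081 without KO replicate 2. Of 20 mesenchymal genes 2 were higher, 12 lower and 6 not called (camera adjusted p = 0.12). Of 28 synaptic genes 5 were higher, 20 lower and 3 not called, with SYT4 at least 132-fold lower. The synaptic list stood above other genes with a median change below 0 (camera adjusted p = 0.027, or 0.61 with an estimated correlation, 0.12 without KO replicate 2 and 0.059 with median-ratio scaling). Of all 41 synaptic genes 23 were at 0 in all KO libraries, and of the 28 tested 13 were, so the filter on mean FPKM may bear on this result. With no filter the synaptic list turned direction.

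The other lists of cell physiology were also mostly lower. Lower members numbered 32 of 35 autophagy genes, 27 of 35 proteasome genes, 15 of 18 neurodegeneration genes and 36 of 39 genes of RNA polymerase II and general transcription factors. Higher members numbered 2, 6, 3 and 2. LAMP1, a lysosomal membrane protein, was at least 116-fold lower and PSMB4, a proteasome subunit, at least 271-fold. Their camera adjusted p values were 0.67, 0.93, 0.84 and 0.37. With no filter the proteasome and neurodegeneration lists turned direction and passed the threshold, as did the proteasome list with quantile normalization. In the integrated stress response 18 of 19 genes were lower and 1 was higher, in the unfolded protein response all 19 were lower, in the heat shock response 15 of 16 were lower and 1 was not called, and among p53 targets 19 of 20 were lower and 1 was higher. The camera adjusted p values were 0.39, 0.073, 0.12 and 0.72. Without KO replicate 2 the unfolded protein list reached 0.0048 and the heat shock list 0.0041.

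Transcripts of histone genes and small structural RNAs mostly lack poly(A) tails. Of 23 replication-dependent histone genes 4 were higher, 8 lower and 11 not called (camera adjusted p = 5.6e-07 upward, or 0.61 with an estimated correlation). Of 41 small structural RNAs 6 were higher, 1 was lower and 34 were not called, and the median change was below 0 although the list stood above other genes (camera adjusted p = 4.2e-17, or 0.091 with an estimated correlation). The small structural RNA list goes by symbol pattern and also holds pseudogene-style names such as RNA5SP108. Of its 982 entries, 956 were at 0 in all KO libraries, but of the 41 tested only 21 were. For histones these numbers were 44 of 72 and 5 of 23. The filter on mean FPKM thus kept members with KO counts more often, so neither camera result can be told apart from this selection. Some higher calls of small RNAs rested on few KO counts, such as 4, 4 and 6 for RNU2-2P and 2, 5 and 1 for RNA5SP108. Adjusted over the list alone, the histone calls were 2 higher and 6 lower, those of small RNAs 2 higher and 0 lower, and the calls of every other list were as over all genes. Copies within both families share reads, so single members are uncertain. Of 4 tested epithelial markers none was called, and the list held 0.00577% ± 0.0024 of the counts in KO and 0.00203% ± 0.0023 in WT, where WT replicate 3 held the most and the mean without it was 0.000702%. Blood and microglial markers, with 1 tested and none called, held 0.00155% ± 0.00093 and 0.000318% ± 0.00024, or 0.00102% in KO without KO replicate 3 and 0.000178% in WT without WT replicate 3. Glial and endothelial markers and olfactory receptors had 0 tested members, and held 0.00153% ± 0.0014 and 0% of the KO counts against 0.000191% ± 0.000088 and 0.000108% ± 0.000035 in WT. Without KO replicate 2 the glial and endothelial share in KO was 0.000964%.

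**Figure D3:**
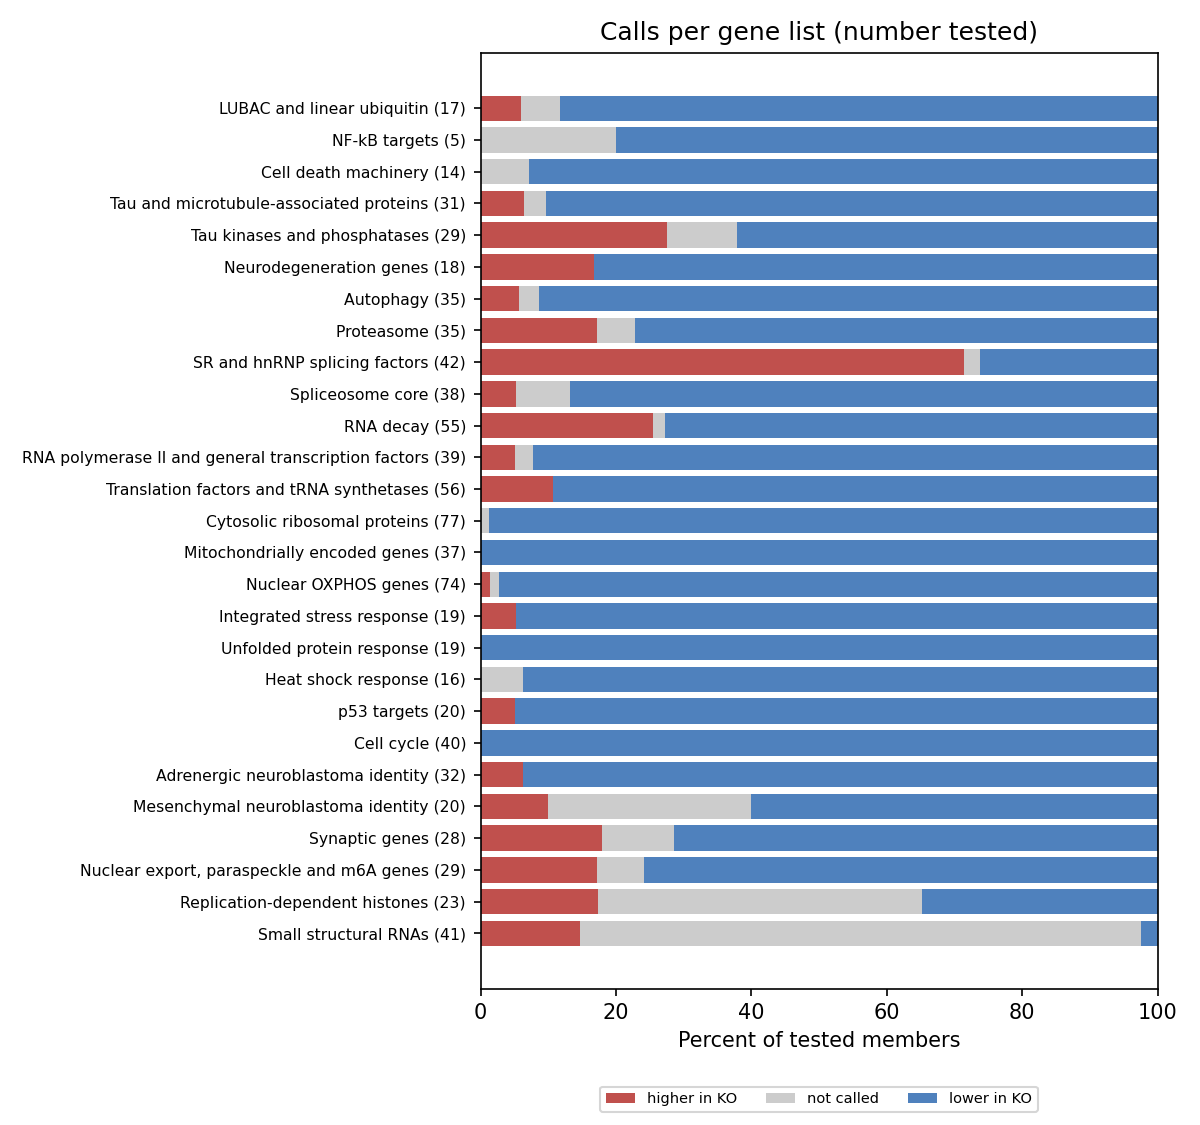
Percent of tested members called higher in KO (red), not called (grey) and called lower in KO (blue) for each gene list with at least 5 tested members, with the number tested in brackets. In the SR and hnRNP list 30 of 42 members were higher, and all 37 mitochondrially encoded genes were lower.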

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

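Library totals without TMM factors, limma on log2(FPKM + 1), WT libraries thinned to the KO depth and leaving out the ribosomal RNA loci were chosen after the results were seen. The total of 10345 changed genes, of 10820 tested, stayed within 1.5 times under all alternatives except 2. It lay between 8788 (quantile normalization) and 14795 (no filter, with about 32860 genes tested). With a mean of at least 5 FPKM it was 4504, 3851 of them lower and 4278 changed at least 2-fold, because 4719 genes were tested. With a replicate block it was 741, with 452 higher, 289 lower and 732 changed at least 2-fold, and all 741 were called the same way without the block. The replicate numbers do not pair the samples: correlations of same-numbered libraries were -0.0013, -0.0111 and 0.0305, and not every library correlated best with its own number. Under that block OTULIN (-12.97) and MAPT (-13.44) had an edgeR adjusted p of 0.094. Quantile normalization gave 4309 higher and 4479 lower genes, with 3045 changed at least 2-fold, and of 8486 genes called both there and with edgeR 5293 had the same direction. It turned OTULIN to 0.31, MAPT to 0.53, RNF31 to 0.44, RBCK1 to 0.12, CYLD to 0.49, TAB3 to 0.78, MAP3K7 to 2.62, CCL2 to 0.24, SOD2 to 1.28 and MAP2 to 0.78 (log2). TAB3, MAP3K7, SOD2 and MAP2 had KO counts, and the others were at 0 in KO. Under every other alternative that tested them OTULIN and MAPT were lower; the 5 FPKM filter left both out. TAB2 turned to -0.10 and GSK3B to -0.15 with median-ratio scaling and with DESeq2. MAP1B was -0.11 with no filter, -0.30 at 5 FPKM, -0.53 with median-ratio scaling and with DESeq2, -0.19 on the TPM scale, and between -0.08 and 0.13 with 1 library left out. MAP3K7 was 0.12 with library totals, 0.34 with thinned WT, 0.06 in 3 limma fits and 0.07 at a pseudocount of 0.1. Of 27 lists, 9 passed the threshold, against 0 with an estimated correlation, 21 with no filter and 5 at 5 FPKM. Camera directions also turned, at these adjusted p values. For linear ubiquitin genes they were 0.91 (library totals), 0.96 (3 limma fits), 0.16 (quantile) and 0.66 to 0.99 (1 library left out). NF-kB targets had 0.09 (no filter), 0.94 (block), 0.95 (3 limma fits), 0.92 (pseudocount 0.1), 0.97 (TPM scale) and 0.57 to 0.99 (1 library left out). Tau and microtubule-associated proteins had 0.84 (block), 0.91 (3 limma fits), 0.74 (pseudocount 0.1) and 0.93 (TPM scale). Translation factors had 0.55 (block), 0.84 (3 limma fits), 0.58 (pseudocount 0.1) and 0.83 (TPM scale). With no filter, tau kinases had 0.99, neurodegeneration genes 0.012, proteasome 0.00024, RNA decay 0.19, mesenchymal genes 0.29, synaptic genes 0.57 and nuclear export genes 0.30. At 5 FPKM, proteasome had 0.89 and mesenchymal genes 0.98, and with library totals proteasome had 0.77. With quantile normalization, autophagy had 0.84, proteasome 0.0011, p53 targets 0.70 and nuclear export genes 0.94. With 1 library left out, the range was 0.63 to 0.87 for neurodegeneration genes, 0.10 to 0.98 for proteasome and 0.63 to 0.80 for p53 targets. Genes at 0 in all KO libraries had no KO counts, so their turns to higher under quantile normalization came from the normalization. The cause of the other turns, for genes and for lists, and of the lower count under the block was not tested. Over all alternatives, 1513 results for single genes other than OTULIN and MAPT kept their direction and side of the threshold, 46 lost the call, 6 gained it and 24 turned, and for lists these numbers were 419, 23, 48 and 47. DESeq2 gave no list tests. The KO depth limits what can be seen: 3 counts over the group are 1.25 CPM.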

Other observations

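The test of degraded RNA, the depth-matched form of the pseudogene test and the count of parent genes were chosen only after the results were seen; the lists of conserved and fast-evolving families were written after the most abundant KO genes had been looked at, and before their detection was counted.

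Processed pseudogenes, copies of spliced mRNAs in the genome, took many counts in the libraries labelled OTULIN KO. For 234 parent genes with such copies, the copies held 48238 counts over the KO group where the WT shares would give 6736. Copies of EEF1A1 alone held 24058 of them. For 27 parents over 50% of the counts lay in the pseudogenes in KO, and for 0 in WT. Parents were kept by their own counts in WT but by parent and copies together in KO, which favours this contrast. Some of the 27 had few KO counts, such as RPS3A with 0 in the parent and 11 in its copies. The share differed from WT for 98 parents (exact binomial test, Benjamini-Hochberg adjusted p under 0.05), higher for 79 and lower for 19, while single WT libraries set at the same counts against the other WT libraries gave 11 to 12. This test pools the reads of 3 libraries and covers counting error only, and replicate libraries differed by more than that. For EEF1A1 the share in pseudogenes was 65.3% in KO and 5.76% in WT.

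Fewer genes were detected in KO than depth gives. WT libraries thinned to the KO totals had 6.78 times as many genes with a count as the KO libraries, above the bound of 2 set before the result was seen, which argues against lower depth as the whole cause. Without the 4 ribosomal RNA loci the ratio was 6.45, which argues against a few abundant genes as the whole cause. What else separates the KO libraries is confounded with genotype, since all 3 differ from WT alike, and a fault in the making or processing of the KO libraries was not tested and stays open. The fold and list changes between KO and WT may therefore not be effects of the loss of OTULIN.

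The genes kept in KO were not a random part of those in WT. If the KO RNA were RNA of another species, of which sequences close to human align, conserved families should be seen more often, and 46.7% of 122 such genes were detected, against a median of 18.9% (95% range 12.3 to 25.4) of lists matched on WT counts; fast-evolving or primate families were detected in 4.23% against 9.42%, and of 1269 long non-coding RNAs 19 were detected against 5.28% in matched lists. This is consistent with that hypothesis, but the conserved list includes calmodulin genes, of which CALM2 had been seen, it may differ from other genes in more than conservation, and no other genome was used here. The share of mitochondrially encoded genes in KO was 0.000497 of that in WT, below a bound of a hundredth for a degraded sample of the same human cells. The test and its bound were set after the value was known, so its outcome was fixed and it does not decide on degradation. Human RNA changed by the loss of OTULIN was expected to keep the median change of the log2 ratio of pseudogene to parent counts within 1 of 0. The planned median was 3.29, past its bound of 2, but 0.5 counts added at low KO counts inflate it. Over the 86 parents with at least 1 expected count it was 1.75, between the bounds of 1 and 2, so the medians leave the question open. The pseudogene share differed from WT for 98 of 234 parents, 79 higher and 19 lower, against 11 to 12 between WT libraries. That count was chosen after the results were seen, and its test pools the KO reads and leaves out the spread between KO libraries. It therefore does not decide the question. A change of the split between parents and pseudogenes by the loss of OTULIN itself was not tested.

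OTULIN and MAPT were at 0 in KO, and so were 78.5% of the 4492 genes with WT counts within 1.5 times of either. This lies between the bounds of 50% and 80% set beforehand, so a specific loss of OTULIN or MAPT transcripts cannot be told apart from the general absence of genes at this level.

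The 6 libraries can be split into 3 and 3 in 10 ways. The real split gave 10345 genes and the highest of the others 0, and 1 of the 10 splits gave as many, but 10 splits are too few for a share under 0.05. Every other split also mixes KO and WT libraries in both groups, so its count was bound to be low and does not bear on chance.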
